A study of Mus musculus with 2 samples.

How the data were processed

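Single-cell RNA sequencing was done on immune cells from the brains of mice that carried GL261 glioma and received anti-PD-1. The labels give 2 samples, 1 library from wild-type mice and 1 from Fcgr2b knockout mice, each from cells pooled from 5 brains and sorted as CD45.2-positive and 7-AAD-negative. Libraries were made with the Chromium 5' kit, version 2, with a target of 10000 cells. The labels give polyA RNA as the molecule of the wild-type library and total RNA as that of the library labelled Fcgr2b knockout, and the sorting protocol names lung where the tissue is given as brain; both were taken as brain cells prepared alike. The processed values are UMI counts per gene and cell barcode as deposited, not normalised; per the file headers the authors made the counts with Cell Ranger 6.1.2, and their processing notes give the genome build as mm10 (GRCm38). The annotation release the authors used is not stated. Both tables hold the same 32285 genes, whole numbers only, and at least 500 UMIs per barcode. Gene coordinates and transcript lengths came from GENCODE for the same build and covered 32158 of the genes by identifier. No receptor sequence libraries were used here.

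Barcodes with at least 200 detected genes and at most 10% mitochondrial UMIs were kept. Doublets were scored in each library as Scrublet does, from 2 simulated doublets per cell, and the highest-scoring cells were removed, as many as 0.8% of barcodes for every 1000 barcodes in the library. That took out 119 cells (3.25%) of the wild-type library and 676 cells (7.66%) of the library labelled Fcgr2b knockout. Mitochondrial UMIs excluded 196 and 373 barcodes and low gene numbers 10 and 13. The 11683 cells left were 3538 from the wild-type library, with a median of 2598 UMIs, and 8145 from the library labelled Fcgr2b knockout, with a median of 3951 UMIs. A count of 0 cells allows a share of up to 0.0848% in the first and 0.0368% in the second, taken as 3 counts.

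Counts were scaled to 10000 per cell and log-transformed for clustering. The 2000 most variable genes, ranked within each library, were reduced to 30 principal components, and a shared-neighbour graph of 15 neighbours was partitioned by the Leiden method at resolution 1, first on all cells and then again within the lymphocyte and the macrophage and microglia groups. Both libraries were clustered together without batch integration. Fcgr2b, mitochondrial, ribosomal protein, antigen receptor, haemoglobin and sex-linked marker genes were left out of the clustering genes. The 31 clusters were named from 22 marker lists. A name needed at least 3 markers at 50 CPM or more with a log2 ratio of at least 1 over the other clusters, and the 10 leading genes of a cluster could not point more strongly to another class. CD8 clusters needed Cd8a or Cd8b1 UMIs in at least 60% of cells and CD4 clusters needed Cd4 UMIs in at least 40%. T cell clusters below these shares were kept apart as mixed T cells, and clusters with a mean log2 ratio of cycling markers of at least 2 were named as cycling. Monocytes, macrophages and border-associated macrophages were counted as 1 class, as were B cells and plasma cells. A cluster of low-UMI cells and a small granzyme-rich cluster were left unnamed. Cell classes are therefore classes of RNA profile.

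For each class, counts were summed per library and divided by the class total to give CPM. Log2 ratios are the library labelled Fcgr2b knockout over the wild-type library with 10 CPM added to each. Fold values are ratios of CPM without this addition, with exact conditional intervals. Levels carry exact Poisson intervals and shares of cells carry exact Clopper-Pearson intervals, all at 95%. Where 1 library had no UMI, the fold was computed against 3 counts and is a lower bound. Expression was compared in the 11 classes with at least 50 cells in each library, leaving out mixed T cells and cycling CD8 T cells. With 1 library per genotype no test between genotypes could be run, so no p-value is given and no gene is called.

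Genes were named by a rule. It took Fcgr2b and, among genes at 100 CPM or more in at least 1 library, the 10 highest and 10 lowest log2 ratios in CD8 T cells and in the macrophage or monocyte class and the 5 highest and 5 lowest in other classes. Mitochondrial, ribosomal protein, antigen receptor, haemoglobin, predicted and sex-linked marker genes were left out of this ranking. The rule also took 2 to 4 members with the largest absolute log2 ratios of each gene list, and Tcf7, Pdcd1, Slamf6, Havcr2, Gzmb, Ifng and Mki67 in CD8 T cells. Values of 2 list members are not reported here. Beside each named gene, the median log2 ratio of the other compared classes and the level that free RNA could give were computed. Free RNA was sized per class and library from 12 macrophage genes as the median ratio of class level to library level.

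The 21 gene lists covered stem-like and memory, exhaustion, cytotoxic, tissue residency, AP-1, immediate-early and dissociation stress, cell cycle, type I interferon, interferon-gamma, MHC class II, immunosuppressive myeloid, pro-inflammatory myeloid, Fc gamma receptor, homeostatic microglia, glycolysis, regulatory T cell activation and B cell activation genes, the neighbours of Fcgr2b on chromosome 1, and erythroid, neural or tumour, and neutrophil genes as markers of other cells. A list was summarised by the median log2 ratio of its members at 20 CPM or more in at least 1 library, where at least 3 were measured. Its interval came from 1000 Poisson redraws, and its percentile from 10000 random lists of the same size drawn among the 100 genes nearest in mean expression to each member. CD8 T cell states were clusters of the CD8 and cycling CD8 classes and of mixed T cells that passed a gate (a Cd3 UMI, a Cd8a or Cd8b1 UMI and no Cd4 UMI), named from 5 state marker lists. Shares of these cells with a UMI were counted after each cell was thinned to 2000 UMIs.

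The filters, the resolution, the marker lists, the gene lists, the rule for naming genes, the intervals and 15 of the 22 alternatives were chosen before the data were examined. The order of the clustering steps and the cut-offs for naming clusters and states were set while the clusters were being read, and the 7 other alternatives were added after seeing the data. These 15 were at least 500 genes, at most 5% mitochondrial UMIs, no doublet removal, Scrublet's automatic threshold, resolutions of 0.5 and 1.5, each library clustered alone, the CD8 gate per cell, median-of-ratios scaling, scaling without mitochondrial and ribosomal protein genes, a pseudocount of 1 CPM, list members without a minimum or at 100 CPM, and thinning to 1000 UMIs or none. Those added were clustering without the 46 genes that differed in the same direction by a log2 ratio of 1 or more in at least 6 classes, shares among cells outside the macrophage or monocyte class, 2 macrophage clusters each taken alone, log2 ratios less the median of the other classes, CD8 counts less free RNA, and log2 ratios less the median of genes of like transcript length.

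The intervals and list percentiles were tested on simulated data with the totals of the 2 libraries. The counts were Poisson draws from a pooled profile, which is what the intervals assume. The shares below therefore check the computation and do not measure spread between cells, clusters or mice. In CD8 T cells, the interval held the true fold for 94% of 100 genes set to 2-fold and 98% of 100 genes set to 4-fold, and for 95.3% of 1272 genes with no difference. In the macrophage or monocyte class these shares were 97%, 97% and 94.8% of 1298 genes. A list of 15 raised genes reached percentile 100 in both. Of 200 lists with no difference, 0% in CD8 T cells and 3.5% in the macrophage or monocyte class fell outside the central 95% of random lists. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9.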

Results

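Mice that carried GL261 glioma received anti-PD-1 at 200 ug on days 10, 13 and 16, and immune cells sorted from their brains on day 20 were compared between wild-type mice and mice labelled Fcgr2b knockout. Macrophages and monocytes were 42.0% of the cells in the library labelled Fcgr2b knockout (3421 cells, interval 40.9 to 43.1%) and 9.41% in the wild-type library (333 cells, 8.47 to 10.4%), a 4.46-fold higher share (3.99 to 5.01). Those macrophages carried 26.1 times as much C1qb and 8.94 times as much Arg1 RNA per count, with the class spread over different clusters in each library. In 2 clusters that both libraries hold, C1qb was 6.94-fold and 5.12-fold higher, the latter from 16 UMIs in the wild-type library and 49 in the other. Free RNA was not sized in single clusters. MHC class II genes were also higher in those macrophages. NK cells were 4.71% against 22.5%, and CD8 T cells took nearly the same share, 14.2% against 12.7%. CD8 T cells of the library labelled Fcgr2b knockout had more Xcl1, Ccl3 and Gzmk and less Tox, Ikzf2 and Gzmc. These are sums over clusters that held similar parts of the class in each library. Finer state clusters, read in a wider CD8 set with cycling and gated mixed T cells, differed more in share. A different make-up within the class could therefore contribute to these differences, which was not tested. Each genotype is 1 library pooled from 5 brains, so there are no replicates and the intervals given, all 95%, cover counting error only. In all pairs of values below the wild-type library comes first, and levels are CPM of the summed counts of the cell class.

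Lymphoid and granulocytic shares differed as well. NK cells had a share ratio of 0.209 (0.185 to 0.237), and mast cells or basophils were 5.2% (184 cells) and 0.258% (21 cells), a 20.2-fold lower share in the library labelled Fcgr2b knockout (12.8 to 33.4). Of the mast cell or basophil class, 106 and 12 cells were in a basophil-like cluster led by Il4, Il6 and Il13, and 78 and 9 cells in a mast cell cluster led by Mcpt1, Mcpt2 and Tpsb2. Neutrophils made up 2.40% and 0.626% (ratio 0.261, 0.180 to 0.373; 0.455 with at least 500 genes per cell), type 1 conventional dendritic cells 2.85% and 1.14% (0.400), and all dendritic cells together 11% and 6.81% (0.618, 0.542 to 0.705). Conventional CD4 T cells were 8.45% and 5.02% (0.594, 0.511 to 0.692) and regulatory T cells 8.51% and 6.86% (0.807, 0.700 to 0.931, but 1.14 without doublet removal). Microglia were 2.12% and 3.94% (75 and 321 cells, 1.86, 1.44 to 2.42), and cycling CD8 T cells 2.60% and 3.63% (1.40, 1.10 to 1.79). Plasmacytoid dendritic cells (1.27% and 1.17%, 0.917, 0.637 to 1.34) and B or plasma cells (2.49% and 1.99%, 0.8, 0.613 to 1.05) had intervals that include 1. T cell clusters with neither a clear CD8 nor a clear CD4 share were 10.1% and 6.58%, and gamma-delta T cells 1.13% and 0.516%.

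The large macrophage share lowers every other share in the library labelled Fcgr2b knockout. Among cells outside the macrophage or monocyte class, CD8 T cells were 14.0% and 24.5%, all T cells 48.0% and 63.5%, regulatory T cells 9.39% and 11.8%, conventional CD4 T cells 9.33% and 8.66%, and dendritic cells 12.2% and 11.7%. NK cells remained lower on this basis, at 24.9% and 8.13%. Microglia were 2.34% and 6.80%. Counted per cell rather than by cluster, cells with a Cd3 UMI, a Cd8a or Cd8b1 UMI and no Cd4 UMI were 15.3% and 19.3% of all cells (ratio 1.26, 1.14 to 1.39), and cells with an Ncr1 UMI and no Cd3 UMI were 3.34% and 1.15% (0.346, 0.261 to 0.458).

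**Figure D1:**
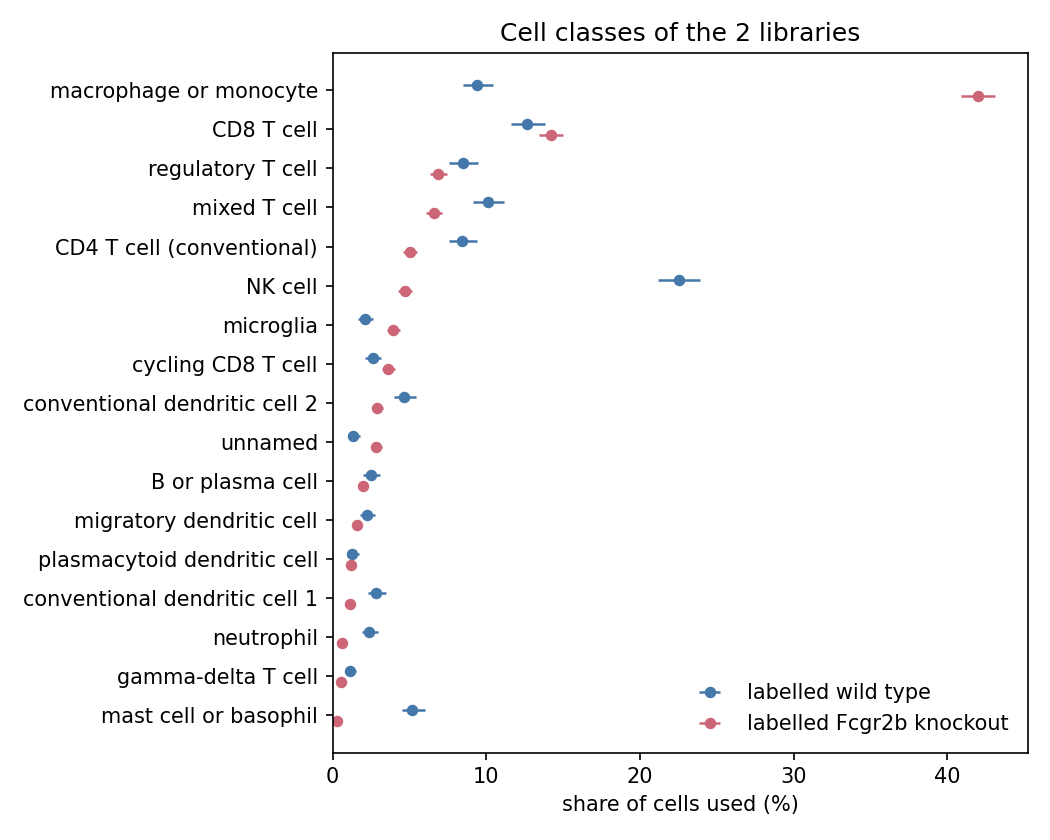
Share of cells used (%, x axis) of each of 17 cell classes (y axis) in the wild-type library and the library labelled Fcgr2b knockout; bars are 95% intervals. Macrophages or monocytes are 9.41% and 42.0% and NK cells 22.5% and 4.71%.

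Fcgr2b (ENSMUSG00000026656, chromosome 1, 170958617 to 170976547), which encodes the inhibitory Fc gamma receptor IIB, was counted in both libraries. In macrophages and monocytes it was 365 CPM (331 to 402, 416 UMIs) in the wild-type library and 249 CPM (241 to 257, 4044 UMIs) in the library labelled Fcgr2b knockout, a ratio of 0.682 (0.617 to 0.756). Microglia had 369 (302 to 447) and 129 CPM (113 to 146), a ratio of 0.348. B or plasma cells had 118 and 76.1 CPM (ratio 0.642), type 1 conventional dendritic cells 55.1 and 31.5, type 2 conventional dendritic cells 122 and 127, neutrophils 137 and 124, and migratory dendritic cells 3.02 and 20.2 (1 and 15 UMIs). NK cells had little, 9.46 and 7.25 CPM. In T cells the order was the other way, with 0 and 46 UMIs in CD8 T cells (0 and 8.31 CPM, at least 4.39-fold higher), 1 and 30 UMIs in conventional CD4 T cells and 1 and 40 in regulatory T cells. Plasmacytoid dendritic cells had 0 and 44 UMIs (at least 4.10-fold higher, 61.5 CPM). Free macrophage RNA was sized at 1.57 CPM of Fcgr2b in CD8 T cells of the library labelled Fcgr2b knockout. The part of the gene deleted is not given in the sources used here, and reads from a 5' library can come from outside it, so these values neither check nor contradict the label.

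**Figure D2:**
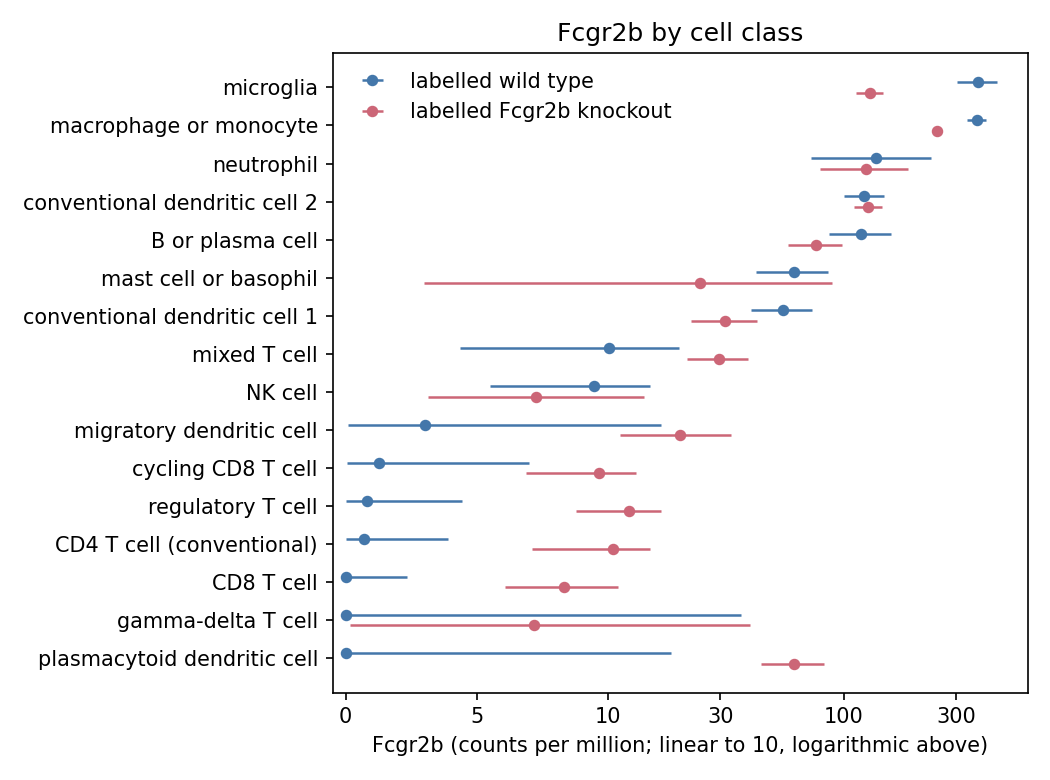
Fcgr2b level in CPM (x axis, linear to 10 and logarithmic above) by cell class (y axis) in the wild-type library and the library labelled Fcgr2b knockout; bars are 95% intervals. Macrophages or monocytes have 365 and 249 CPM.

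In macrophages and monocytes of the library labelled Fcgr2b knockout, Chil3, Vcan and Ccr2 were among the lower genes and the complement C1q genes, Arg1 and Nos2 among the higher. Chil3 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), which encodes the monocyte lectin Ym1, was 1899 and 29.8 CPM, a ratio of 0.0157 (0.0142 to 0.0173). Vcan (230.0 and 15.8) and the chemokine receptor gene Ccr2 (469 and 132, ratio 0.281) were lower in the library labelled Fcgr2b knockout. So were the progenitor granule genes Elane (239 and 0.0616, 1 UMI; ratio 0.000258, 6.51e-06 to 0.00145), Mpo (171 and 0.308, 5 UMIs) and Prtn3 (166 and 5.61), and Eps8 (218 and 3.76). The complement genes C1qb (ENSMUSG00000036905, chromosome 4, 136880129 to 136886187; 127 and 3320.3, 26.1-fold, 22.2 to 30.9), C1qa (77.2 and 1689, 21.9-fold) and C1qc (74.6 and 1634, 21.9-fold) were higher, as were the chemokine gene Ccl8 (17.6 and 639, 36.4-fold) and Chil1 (0 and 136, at least 51.7-fold). Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484; 151 and 1350.0, 8.94-fold, 7.70 to 10.5) and Nos2 (30.7 and 371, 12.1-fold, 8.67 to 17.3), which encode the arginine-consuming enzymes arginase 1 and inducible nitric oxide synthase, were higher together. Hebp1 (7.90 and 146) and the interferon-induced gene Ifi44 (5.27 and 154, 29.2-fold) were also higher.

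Genes of the Ifi200 family of DNA sensors, which lie near Fcgr2b on chromosome 1, had some of the largest ratios of the class in both directions. Ifi202b (ENSMUSG00000026535, chromosome 1, 173962568 to 173982744) was 0 and 249 CPM, at least 94.5-fold higher in the library labelled Fcgr2b knockout, while Ifi213 (198 and 1.42), Ifi211 (714 and 52.9) and Ifi206 (141 and 5.85) were lower. In the other classes these 4 had median log2 ratios of the same direction, 3.22, -2.44, -1.30 and -1.55. The non-coding AI506816 on chromosome 5 was also lower (391 and 20.1; -1.29 in other classes). The whole list of Fcgr2b neighbours, which has the SLAM, Fc receptor and Ifi200 families, had a median log2 ratio of -0.32 in macrophages and monocytes, at percentile 7.03 of random lists.

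Antigen presentation stood out among the gene lists of this class. All 7 measured MHC class II genes were higher in the library labelled Fcgr2b knockout, with a median log2 ratio of 2.47 (2.43 to 2.52), and H2-Eb1 (740 and 6226, 8.41-fold), H2-Ab1 (1215 and 8248, 6.79-fold), H2-Aa (1099 and 6818, 6.2-fold) and Ciita (29.8 and 73.6) were among them. H2-Aa and H2-Eb1 were higher by a log2 ratio of 1 or more in 8 and 6 of the 11 classes compared. Less the other classes, the list median was smaller, as given below. The log2 ratio of all genes had a median of -0.13 here, and list medians below, in all classes, are given relative to that of all genes in the class. The immunosuppressive myeloid list was 1.76 higher (13 of 16 genes higher, percentile 100), and the pro-inflammatory list 0.80 higher (12 of 15, percentile 99.98). The size of the immunosuppressive difference depended on the scaling, the minimum level of members and the cluster taken, as given below. Il1a (19.3 and 202, 10.4-fold), the neutrophil chemokine gene Cxcl2 (1145 and 5688, 4.97-fold), Ptgs2 (233 and 912, 3.91-fold) and Ccl5 (337 and 2863, 8.50-fold) were higher, and Tnf less so (246 and 479). The interferon-gamma list was 0.41 higher (percentile 98.5) with the PD-L1 gene Cd274 at 253 and 685 (2.71-fold) and Iigp1 at 127 and 311. The type I interferon list was at -0.13 (percentile 28.0), with Ifit1 lower (178 and 80.9), Ifit2 lower (205 and 110) and Usp18 lower (133 and 70.2).

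The Fc gamma receptor and signalling list had a relative median of 0.05 (percentile 60.8), with its signal chain gene Fcer1g higher (1770 and 3129, 1.77-fold) and the kinase genes Lyn (533 and 277) and Fgr (161 and 65.6) lower. Glycolysis genes were 0.41 higher (percentile 95.7) with Aldoa (240 and 703, 2.93-fold) and Gapdh (799 and 1609), and the AP-1 list was 0.24 higher with Fosb (449 and 1230.0) and Fos (1084 and 2547, 2.35-fold). The stress list was 0.21 higher with Dusp1 (1165 and 2207) above and Hspa1b (1292 and 647) below, and the cell cycle list 0.30 lower, with Mcm6 at 21.1 and 3.82. Lists defined for T or B cells had cytotoxic genes at 0.65 (percentile 99.4, from Ccl5 and Tnf among others), exhaustion at 0.55 (Cd38, 29.8 and 117), stem-like at -0.09 (Il7r, 5.27 and 81.2), residency at -0.12 (Rgs1, 193 and 1333), regulatory T cell activation at 1.01 (3 genes, Tnfrsf9 10.5 and 33.9) and B cell activation at -0.16 (Fas, 80.8 and 30.7). Homeostatic microglia genes were at 0.25 with Tmem119 (2.63 and 21.6) higher and Cx3cr1 (95.7 and 34.4) lower. Erythroid and neural or tumour genes had fewer than 3 measured members in every class.

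Clusters within the class were taken up unevenly by the libraries. A monocyte cluster led by Vcan, F13a1 and Chil3 held 60.7% of the class in the wild-type library and 2.28% in the library labelled Fcgr2b knockout, and 5.71% and 0.958% of all cells. A cluster led by Cd14 and Il1b held 6.31% and 33.3% of the class, a cluster with Apoe, complement genes and Gpnmb 2.40% and 16.3%, and clusters with Arg1 and Nos2 1.80% and 14.9% (also Ccl8) and 1.2% and 11.1% (also Ly6i). Only an interferon-responding cluster led by Slfn4 and Ms4a4c had a similar part of the class, 21.0% and 17.8%. In that cluster MHC class II genes were still 1.36 higher (7 of 7), interferon-gamma genes 0.88 higher (17 of 17) and type I interferon genes 0.60 higher (15 of 16), with Irf1 at 344 and 942 (2.74-fold), Cxcl10 at 701 and 1870 (2.67-fold), Cd274 at 376 and 988 and Isg15 at 1661 and 3281. The monocyte cluster had MHC class II genes 2.45 higher (H2-Aa 292 and 1900, 6.51-fold) and type I interferon genes 0.78 higher (16 of 16; Rsad2 624 and 1841, 2.95-fold). Its immunosuppressive list was at 0.08 with members far apart, Chil3 at 2542 and 202 and C1qb at 20.8 and 106. Cell cycle genes were 1.07 lower there (0 of 9 higher) and neutrophil genes 1.85 lower, with S100a8 at 135 and 17.3. Fcgr2b itself was 346 and 169 CPM in the monocyte cluster and 339 and 210 in the interferon-responding cluster.

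Microglia of the library labelled Fcgr2b knockout had more antigen presentation and interferon-gamma RNA and less of their homeostatic genes. MHC class II genes were 2.27 higher than the all-gene median of -0.21 (8 of 8), with H2-Aa at 997 and 5455 (5.47-fold, 4.87 to 6.18) and H2-Oa at 41.8 and 333. Interferon-gamma genes were 1.02 higher (15 of 16), with Gbp2 (146 and 492, 3.36-fold), Psmb9 (73.2 and 254) and the T cell chemokine gene Cxcl9 (129 and 347, 2.69-fold), and type I interferon genes 0.61 higher, with Isg15 at 258 and 467. The homeostatic list was 0.34 lower (9 of 12 genes, percentile 0.61), with Fcrls (ENSMUSG00000015852, chromosome 3, 87250758 to 87263738), a microglial Fc receptor-like gene, at 509 and 29.3 (ratio 0.0576), the fractalkine receptor gene Cx3cr1 at 1289 and 721 (0.559), P2ry13 at 90.6 and 54.8 and Olfml3 at 418 and 267. Stress genes were lower by 0.34 (13 of 14), with Nr4a1 at 2464 and 1230.2 (0.499), and Il1b was 1798 and 891. Ccl8 (13.9 and 116, 8.33-fold), Cxcl13 (3.48 and 104, 1 UMI in the wild-type library; 29.7-fold, 5.27 to 1180.3) and Ifi202b (0 and 207, at least 19.8-fold) were higher. Spint1 (174 and 11.9), Hist1h3d (136 and 23.3), F11r (376 and 82.4) and Slx1b (115 and 21.2) were lower.

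CD8 T cells of the library labelled Fcgr2b knockout had more Xcl1, Ccl3 and Gzmk RNA and less RNA of the exhaustion regulator Tox. The chemokine gene Xcl1 (ENSMUSG00000026573, chromosome 1, 164931644 to 164935527), whose product attracts type 1 dendritic cells, was 29.7 and 187 CPM (6.31-fold, 4.71 to 8.64). Ccl3 (163 and 526, 3.22-fold, 2.83 to 3.67), Ccl4 (846 and 2054, 2.43-fold, 2.29 to 2.57) and Ccl5 (4127 and 8992, 2.18-fold, 2.12 to 2.24) were higher, although Ccl5 had a median log2 ratio of 1.38 in other classes too and Ccl3 of 0.87. Gzmk (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908), a granzyme of effector memory cells, was 56.2 and 181 (3.23-fold, 2.60 to 4.06), and the inhibitory receptor gene Tigit 73.8 and 168 (2.27-fold, 1.87 to 2.78). Tigit had a median log2 ratio of 0.92 in 4 other classes, near its 1.08 here. The NK receptor gene Klrc2 was 49.8 and 199 (4.00-fold), with 1.26 in other classes. S100a10 (606 and 1629) and S100a11 (326 and 771) were higher here and in other classes (1.00 and 1.11). Cd74, at 14.5 and 117, was no higher than free RNA could give (123).

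Tox (ENSMUSG00000041272, chromosome 4, 6686353 to 6991557), a driver of the exhausted state, was 116 and 41.7 CPM (0.359, 0.295 to 0.439), and Ikzf2 (ENSMUSG00000025997, chromosome 1, 69531214 to 69687245), which encodes Helios, was 171 and 45.0 (0.263, 0.221 to 0.314). Their median log2 ratios in other classes were 0.09 and 0.14. Gzmc, a granzyme of strongly stimulated killer cells, was 348 and 124 (0.356, 0.318 to 0.399) over the class, and the inhibitory receptor gene Lilrb4a 162 and 60.3. In the wider CD8 set used for states, a cluster led by Gzmc and Gzmf held 23.4% and 3.46% of cells. Whether the class level of Gzmc only reflects this share was not tested. Odc1, the first enzyme gene of polyamine synthesis, was 293 and 96.1 (0.327) and was lower in other classes as well (-0.88). Cct6a (415 and 157) and Sfn (103 and 38.1) were lower, as were Slx1b (104 and 19.1), Ifi206 (105 and 25.8) and AI506816 (107 and 41.5), which had medians of -2.21, -1.70 and -1.42 in other classes.

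Of the markers fixed beforehand, Slamf6 and Ifng differed most. Pdcd1, which encodes the drug target, was 302 and 305 CPM (1.01, 0.912 to 1.12), Tcf7 31.5 and 25.5 (0.807, 0.581 to 1.14), Gzmb 1996 and 1866 (0.935, 0.898 to 0.973), Havcr2 99.7 and 134 (1.35, 1.13 to 1.61) and Mki67 30.9 and 41.7 (1.35, 0.988 to 1.88). Slamf6 was 19.6 and 40.1 (2.05, 1.40 to 3.09) and Ifng 380 and 646 (1.70, 1.56 to 1.86). Ifng had a log2 ratio of 0.75, near its median of 0.73 in other classes. Gzmb, at -0.10, had a median of 0.90 in 10 other classes. Slamf6 is among the listed neighbours of Fcgr2b on chromosome 1 (171917515 to 171953170). Its median was 0.11 in other classes, and it was higher in NK cells too (12 and 48 UMIs). The CPM values leave out the class of cycling CD8 T cells (92 and 296 cells). The shares that follow are of the wider CD8 set used for states, which includes cycling and gated mixed T cells. With each cell thinned to 2000 UMIs, 9.56% and 7.21% of these CD8 cells had a Tcf7 UMI, 35.3% and 35.1% Pdcd1, 2.22% and 8.37% Slamf6, 14.7% and 18.6% Havcr2, 67.3% and 69.1% Gzmb, 34.9% and 42.4% Ifng and 18.2% and 19.5% Mki67. The Slamf6 shares were 2.43% and 4.33% when thinned to 1000 UMIs, and the ratio for Ifng, 1.21, was 0.963 with at most 5% mitochondrial UMIs. Macrophages, as a measure of free RNA and doublets, had a Gzmb UMI in 2.26% and 6.68% of cells and Ifng in 0% and 2.27%. In B or plasma cells (45 and 132 cells) these shares were 2.22% and 11.4% for Gzmb and 2.22% and 3.79% for Ifng. Slamf6 was in 3.77% and 4.72% of macrophages, above the CD8 share in the wild-type library, and Havcr2 in 10.6% and 13.3%. For these 2 genes the macrophage share cannot serve as that measure. Free RNA of Slamf6 was sized at 0.0988 and 0.477 CPM in CD8 T cells.

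Among CD8 lists, the all-gene median was -0.13 and most medians lay close to it. Type I interferon genes were 0.33 higher (percentile 99.0; Ifi27l2a 1531 and 2271, Isg20 143 and 214, but Ifit1 77.6 and 48.8) and residency genes 0.31 higher (96.8), where the integrin genes Itgae (22.1 and 35.8, 1.62-fold, 1.13 to 2.39) and Itgb1 (151 and 235) were higher and Runx3 (423 and 224, 0.529) lower. The cytotoxic list was at 0.18 (percentile 76.6), the stem-like list at -0.07 (22.9; Bcl2 226 and 99.7, Satb1 302 and 179) and the exhaustion list at -0.06 (24.2; Lag3 520 and 333, 0.640, 0.589 to 0.695; Cd244a 34.7 and 17.7). Interferon-gamma genes were at 0.12 (84.4), with Cxcl10 lower (71.3 and 24.6) and the immunoproteasome gene Psmb9 higher (199 and 317), glycolysis genes at 0.12 (70.5; Aldoa 316 and 414), cell cycle genes at 0.05 (61.0; Stmn1 87.1 and 135), AP-1 genes at 0.01 (34.6; Junb 1722 and 940.0, 0.546) and stress genes at -0.02 (24.1; Dusp1 329 and 184). Regulatory T cell activation genes were at -0.06 (25.2; Nt5e 68.8 and 39.2), Fc receptor signalling genes at -0.16 (20.9; Inpp5d 160 and 128), B cell activation genes at -0.20 (2.63; Prdm1 74.4 and 48.0) and Fcgr2b neighbours at -0.11 (17.1; Ifi213 62.5 and 0.903, Ifi208 73.2 and 36.1). Myeloid lists were higher (MHC class II 1.94, pro-inflammatory 1.40, immunosuppressive 0.70), where C1qb (0.631 and 22.0), Apoe (5.05 and 35.2), Il1b (1.89 and 35.6) and H2-Aa (2.52 and 45.9) are macrophage genes found also in free RNA.

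**Figure D3:**
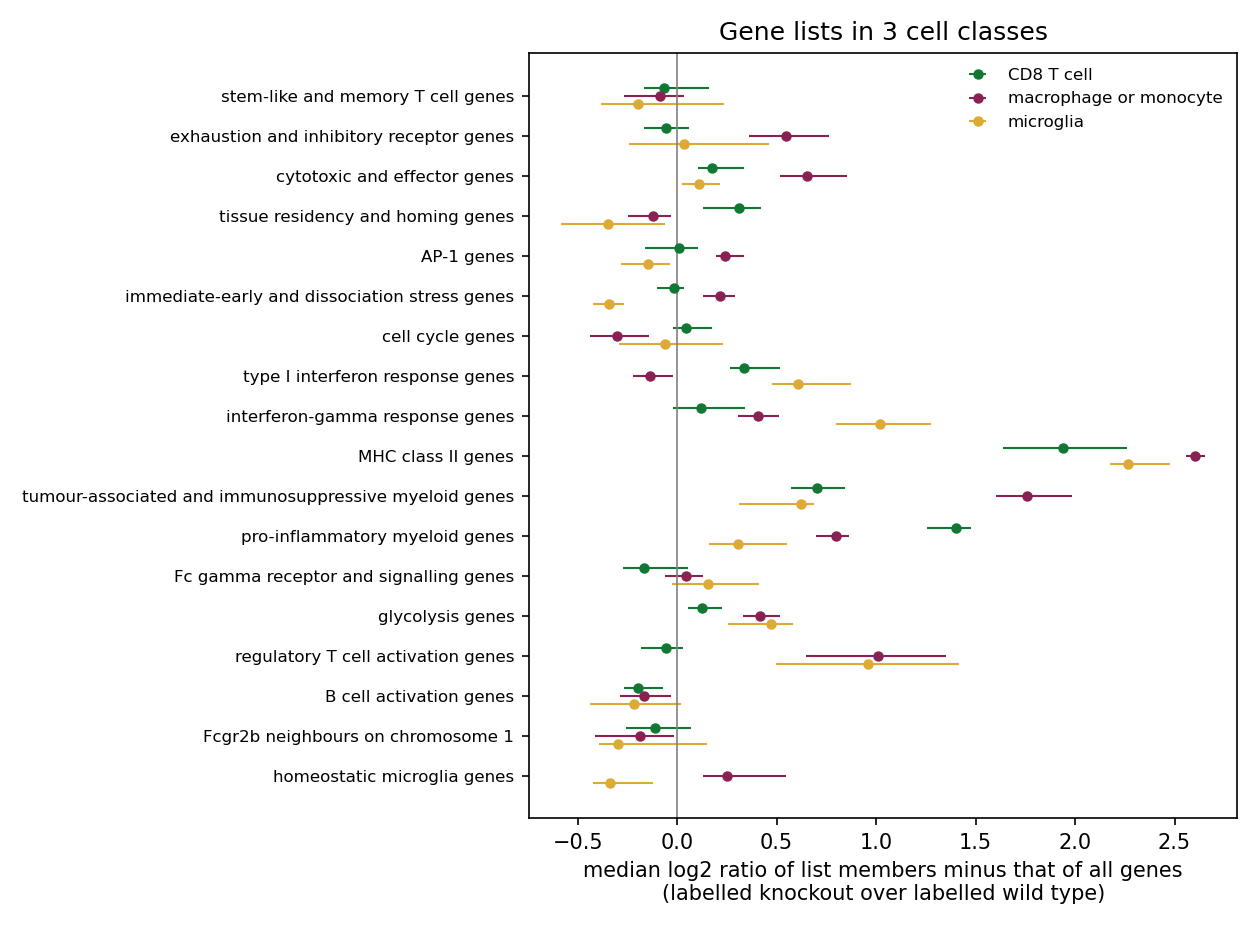
Median log2 ratio of list members (library labelled Fcgr2b knockout over wild-type library) minus that of all genes (x axis) for 18 gene lists (y axis) in CD8 T cells, macrophages or monocytes, and microglia; bars are 95% intervals. MHC class II genes are at 1.94, 2.60 and 2.27.

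CD8 T cell states were read in 610 and 1647 cells. Stem-like cells were 23.6% (20.3 to 27.2%) in the wild-type library and 13.8% (12.2 to 15.5%) in the library labelled Fcgr2b knockout, a ratio of 0.584 (0.472 to 0.725). Cycling cells were 15.1% and 21.1% (1.40, 1.11 to 1.78), interferon-responding cells 13.8% and 20.3% (1.48, 1.16 to 1.90) and exhausted cells 16.6% and 20.5% (1.24, 0.990 to 1.56), and 31.0% and 24.2% had no state by the markers. With at most 5% mitochondrial UMIs the ratios were 0.968 for stem-like, 1.04 for cycling and 0.581 for exhausted cells, and with the libraries clustered alone cycling cells had 9.71. Among the clusters without a state, 1 led by the granzyme genes Gzmc and Gzmf with Klra5 was 23.4% and 3.46% (0.148, 0.107 to 0.202), and 1 led by Itgae and Ccl5 was 5.41% and 17.1% (3.16, 2.20 to 4.69). No cluster was named as effector cells, and Klrg1, an effector marker, had 3 and 80 UMIs in CD8 T cells (7.63-fold, 2.52 to 37.8).

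Regulatory T cells of the library labelled Fcgr2b knockout had more chemokine RNA, a higher cytotoxic list and less of their activation genes. The cytotoxic list was 0.75 higher than all genes (15 of 18 genes), with the chemokine genes Ccl5 (446 and 1655, 3.71-fold), Ccl3 (89.0 and 348, 3.91-fold) and Ccl4 (336 and 1119). Ccl5 and Ccl3 were not particular to these cells: over the compared classes other than NK cells their median log2 ratios were 1.23 and 1.01. The activation list was at -0.30 (13 of 17 lower, percentile 0.07). Lrrc32, which encodes the TGF-beta anchor GARP (289 and 146, 0.505), the IL-33 receptor gene Il1rl1 (277 and 147), the OX40 gene Tnfrsf4 (1330.5 and 765, 0.575) and Il10 (295 and 190) were lower. Tigit was 166 and 391 (2.35-fold), Pdcd1 129 and 189, and Mki67 232 and 443 (1.91-fold). Ly6c2 (20.7 and 194, 9.40-fold) and Lgals3 (30.2 and 148) were higher, and Odc1 (1793 and 251), Mt2 (193 and 47.7) and Cxcr4 (423 and 146) lower. Conventional CD4 T cells likewise had a higher cytotoxic list (0.66, 13 of 17 genes; Ccl5 133 and 349, Ccl3 395 and 803) and more Tigit (110 and 245, 2.24-fold), S100a11 (458 and 1042), Lgals3 (140 and 319) and Spp1 (115 and 260). Their helper cytokine genes Il21 (119 and 45.2, 0.381) and Csf2 (428 and 185, 0.432) were lower, as were Lag3 (971 and 565), Odc1 (918 and 233) and Tuba1c (220 and 70.1). The CD4 stress list was at -0.28 (12 of 14 lower, percentile 0.11) and the type I interferon list at 0.34 (9 of 10 higher).

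The lowest ratios in NK cells were those of Klri2, Klrb1b and Klra8, all NK receptor genes. Klri2 (ENSMUSG00000043932, chromosome 6, 129729041 to 129740484) was 205 and 1.81 CPM (2 UMIs in the library labelled Fcgr2b knockout; 0.00882, 0.00106 to 0.0321), Klrb1b 402 and 14.5 (0.0360) and the Ly49 receptor gene Klra8 522 and 51.6 (0.0990). Klra5 (16.1 and 105, 6.51-fold) and Klra1 (51.2 and 188, 3.68-fold) were higher. Lpin1 (118 and 22.6) and Styk1 (129 and 29.0) were lower, and Emp1 (24.5 and 163, 6.66-fold) and Lgals3 (44.5 and 176) higher. The maturation markers Klrg1 (20.6 and 80.6, 3.91-fold) and Cx3cr1 (5.01 and 31.7, 6.33-fold) were higher, as were Ccl5 (3993 and 10768, 2.70-fold) and Xcl1 (569 and 1013), and the cluster led by Serpinb9b and Klrg1 held 6.15% and 37.8% of NK cells. The cytotoxic list as a whole was at 0.15 (9 of 18 higher), the residency list at -0.27 (percentile 2.32; Runx3 537 and 267) and the exhaustion list at -0.16 (Lag3 76.3 and 29.9). Cd74, at 36.7 and 271, was near the level of free RNA (208).

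Type 1 conventional dendritic cells had higher cell cycle genes in the library labelled Fcgr2b knockout (0.66 above all genes, 11 of 14, percentile 100), with Pclaf at 12.9 and 147 (11.4-fold), Rrm2 at 10.5 and 48.8 and Stmn1 at 45.7 and 148. Il12b, which encodes the IL-12 p40 chain, was 4.69 and 59.8, Ifi44 18.8 and 133, Qpct 69.2 and 238 and Hmgn2 39.9 and 135. Ifi205 (960 and 232), Klrb1b (275 and 47.2), Wfdc17 (219 and 45.7), Kmo (101 and 18.1) and Hmgcs1 (103 and 21.3) were lower. In migratory dendritic cells, type I interferon genes were 0.88 higher (13 of 15; Bst2 178 and 447) and MHC class II genes 0.92 higher (8 of 8; Ciita 27.2 and 82.1), with Ly6a (148 and 810), Ly6e (109 and 576), Plac8 (118 and 538), Ly6i (6.05 and 143, 2 UMIs in the wild-type library) and Cxcl2 (24.2 and 164) higher and Ptcra (112 and 5.38), Irf4 (106 and 25.6), Cish (227 and 63.2) and Idi1 (148 and 43.1) lower. Type 2 conventional dendritic cells had MHC class II genes 0.60 higher (8 of 8), Timd4 at 4.57 and 170 (37.3-fold) and Ifi202b at 0 and 224 (at least 65.4-fold). C1qb (4.57 and 391), C1qa (1.14 and 220, 1 UMI in the wild-type library) and C1qc (1.14 and 236, 1 UMI) were higher there. Free RNA was sized at 441, 243 and 236 CPM of these genes in the library labelled Fcgr2b knockout. That sizing took 28.0% of the UMIs of the class as free RNA, against 2.86% in type 1 conventional dendritic cells. It therefore cannot tell free RNA from macrophage genes that the cells of this class express themselves. Icos (191 and 22.3), Maf (143 and 9.04), Rora (103 and 4.22), Satb1 (154 and 12.7) and Fabp5 (175 and 17.5) were lower in that class, where 17.6% of the cells of both libraries together had a Cd3 UMI.

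Jchain, the antibody joining chain gene, was lower in B or plasma cells of the library labelled Fcgr2b knockout, at 9153 and 1152 CPM (0.126). B cells and plasma cells are 1 class here, so a lower part of plasma cells would give the same. Xbp1 (653 and 106), Prdm1 (44.7 and 7.74), Derl3 (129 and 6.45), Creld2 (521 and 47.7), Ly6c2 (2008 and 249) and Mt1 (450 and 15.5) were also lower. Slpi (34.2 and 2196, 64.2-fold), Gzmc (0 and 228, at least 28.9-fold), Ccl22 (5.26 and 172, 2 UMIs in the wild-type library), Ctse (2.63 and 103, 1 UMI) and Ccl5 (10.5 and 197) were higher. Gzmc and Ccl5 are genes of T and NK cells. With each cell thinned to 2000 UMIs, 2.22% and 11.4% of B or plasma cells (of 45 and 132) had a Gzmb UMI. Whether doublets or other cells give Gzmc and Ccl5 here was not tested. MHC class II genes were 0.90 higher (7 of 8), interferon-gamma genes 0.40 higher, and the B cell activation list was at 0.04 (percentile 52.7). In neutrophils (85 and 51 cells) the pro-inflammatory list was at -2.27 (12 of 13 lower): Tnf was 2989 and 168, Il1a 947 and 48.7, Cxcl3 937 and 10.8 (2 UMIs in the library labelled Fcgr2b knockout), Il23a 189 and 0 (at least 11.7-fold lower) and Bcl2a1a 358 and 16.2 (3 UMIs). Cell cycle genes were higher (2.09, 15 of 17), with Top2a at 31.6 and 503, Mki67 at 42.1 and 530 and Birc5 at 0 and 184 (at least 5.83-fold). The granule genes of immature neutrophils were higher, with Camp at 4157 and 29478 and Lcn2 at 1726 and 6382, and the neutrophil list was at 0.99 (5 of 5). BC018473 (0 and 363), Rgs16 (0 and 179), H2-Aa (0 and 179) and Hspa1b (10.5 and 357, 1 UMI in the wild-type library) were also higher.

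Some differences ran through nearly all cell classes. Slx1b was lower in all 11 classes compared, and 46 genes differed in the same direction by a log2 ratio of 1 or more in at least 6 classes. They include Ctse (higher in 10), the mitochondrial genes mt-Atp8 (higher in 11; 85.2 and 403 CPM in CD8 T cells) and mt-Nd3 (lower in 8), and Ifi202b. Also among the 46 were Apoe (higher in 9 classes), H2-Aa (8), C1qb and Ccl5 (7), and H2-Eb1, Lgals3, S100a10 and S100a11 (6), which are named above for single classes. Genes with short transcripts had higher ratios than genes with long ones. In CD8 T cells the median log2 ratio was 0.32 for genes with transcripts under 1200 nt, -0.07 from 1200 to 4000 nt and -0.27 above 4000 nt, and in macrophages 0.18, -0.16 and -0.40. The order was the same in every class but B or plasma cells (0.29, 0.11 and 0.12).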

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

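Each choice was replaced in turn by 1 of 22 alternatives, 15 chosen before the data were examined and 7 after, and 586 values of 50 results were compared with the main ones. Of these, 468 stayed within the interval of the main value (within 1.5-fold for counts of named genes), 111 left it, and 7 lay on the other side of no difference from a main value whose interval excluded no difference. The Fcgr2b ratio in microglia (0.323 to 0.431), the mast cell or basophil share ratio (0.0357 to 0.0774) and the interferon-responding CD8 state (1.24 to 1.57) held under every alternative that gave a value. Of the 20 genes named from CD8 T cells, 16 to 20 kept their direction, and of the 20 from macrophages, 18 to 20 did. Except where said, the cause of a difference was not tested.

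The share of macrophages or monocytes, 4.46-fold higher at first, was 3.64-fold higher with at most 5% mitochondrial UMIs, 3.76-fold with the automatic doublet threshold, 3.9-fold without doublet removal and 3.7-fold at resolution 1.5. With at most 5% mitochondrial UMIs the share ratios of B or plasma cells (1.3 for 0.8), CD8 T cells (1.27 for 1.12) and microglia (1.43 for 1.86) differed too. Shares outside the macrophage or monocyte class gave ratios of 1.25 for B or plasma cells, 0.928 for conventional CD4 T cells (0.594 of all cells), 1.75 for CD8 T cells, 0.327 for NK cells, 0.965 for dendritic cells (0.618 of all cells), 2.9 for microglia, 0.407 for neutrophils and, on the other side, 1.26 for regulatory T cells (0.807 of all cells). Regulatory T cells also had 1.14 without doublet removal. With the libraries clustered alone CD8 T cells had 0.921, below 1, and NK cells 0.182 (0.209 at first), and the CD8 gate per cell gave 1.26. At least 500 genes gave 0.455 for neutrophils (0.261 at first).

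CD8 states depended most on the choices. Exhausted cells, 1.24-fold higher at first, had 0.581 with at most 5% mitochondrial UMIs, 3.83 with the automatic doublet threshold, 0.816 at resolution 0.5, 1.81 at resolution 1.5 and 0.746 with the gate, so their direction is not settled. Stem-like cells (0.584) had 0.968 with at most 5% mitochondrial UMIs and 0.409 with the libraries clustered alone, and cycling cells (1.40) had 1.04 and 9.71. The ratio of CD8 cells with an Ifng UMI, 1.21 at first, was 0.963 with at most 5% mitochondrial UMIs.

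Fcgr2b in macrophages, at 0.682 at first, was 0.605 with at least 500 genes, 0.765 with median-of-ratios scaling and 0.488 in the monocyte cluster alone. MHC class II genes in macrophages, at a median log2 ratio of 2.47 (list medians in this section are not relative to all genes), were at 2.36 both with at most 5% mitochondrial UMIs and with the libraries clustered alone, 2.58 with the automatic doublet threshold, 2.56 without doublet removal, 2.59 at resolution 1.5, 2.64 with median-of-ratios scaling, 2.4 with scaling without mitochondrial and ribosomal genes, 2.55 with members at 100 CPM, 1.97 without a minimum, 2.39 less genes of like length, 1.43 less the other classes, 1.24 in the interferon-responding cluster alone and 2.33 in the monocyte cluster alone. Immunosuppressive genes, at 1.63, were at 1.06 with median-of-ratios scaling, 0.89 without mitochondrial and ribosomal genes, 2.4 with members at 100 CPM, 0.92 without a minimum, 1.01 less the other classes, 1.14 in the interferon-responding cluster and -0.03 in the monocyte cluster.

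In CD8 T cells, the exhaustion list (-0.19) was at -0.02 with median-of-ratios scaling, -0.07 at resolution 0.5 and -0.07 less the other classes. The cytotoxic list (0.04) was at 0.2 with median-of-ratios scaling, and the stem-like list (-0.20) at 0.09 with at most 5% mitochondrial UMIs and -0.31 with the libraries clustered alone. The NK cytotoxic list (0.09) was at -0.04 with members at 100 CPM and -0.15 less the other classes. No value came from type 2 conventional dendritic cells at resolution 0.5 or from mast cells or basophils with the libraries clustered alone, because no cluster took the name.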

Other observations

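The explanations in this section, and which values would test them, were chosen after the results they examine had been seen. The setting with at least 500 genes had been planned as an alternative filter.

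Xcl1 and its target cell differed in opposite directions. Xcl1, whose receptor Xcr1 marks type 1 conventional dendritic cells, was 6.31-fold higher in CD8 T cells of the library labelled Fcgr2b knockout and also higher in its NK cells (569 and 1013 CPM), while type 1 conventional dendritic cells were 2.85% and 1.14% of cells and 3.15% and 1.97% of cells outside the macrophage or monocyte class. The dendritic cells present had more Il12b (4.69 and 59.8 CPM) and more cell cycle RNA. Cxcl9, which draws T cells with Cxcr3, was 129 and 347 CPM in microglia and 354 and 620 in migratory dendritic cells but 757 and 708 in macrophages, and Ccl5 was 337 and 2863 in macrophages. Ifng was 1.70-fold higher in CD8 T cells, with a median log2 ratio of 0.73 in other classes. MHC class II genes had median log2 ratios (not relative to all genes) of 2.06 in microglia, 2.47 in macrophages, 0.83 in migratory dendritic cells, 0.95 in B or plasma cells, 0.48 in type 2 and 0.14 in type 1 conventional dendritic cells. No link between Ifng and these genes was tested.

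In NK cells, genes of a single complex on chromosome 6 went both ways. Klri2 (205 and 1.81), Klrb1b (402 and 14.5) and Klra8 (522 and 51.6) were lower, and Klra1 (51.2 and 188) and Klra5 (16.1 and 105) were higher. Klrb1b was also 275 and 47.2 in type 1 conventional dendritic cells, and Klrc2 of the same complex was 49.8 and 199 in CD8 T cells. Neutrophils, few as they are (85 and 51 cells), had granule and cell cycle genes of precursors (Camp 4157 and 29478, Mki67 42.1 and 530) in place of inflammatory genes (Tnf 2989 and 168, Ptgs2 1863 and 168).

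Fcgr2b UMIs were found in T cell classes and plasmacytoid dendritic cells of the library labelled Fcgr2b knockout and hardly in those of the wild-type library. Free RNA or doublets with macrophages could give such UMIs, but only 15.9 were expected from 12 macrophage genes and 116 were counted in CD8, conventional CD4 and regulatory T cells, 7.31 times as many (6.04 to 8.77), so they do not account for the whole, although Fcgr3 and Ctsb alone would predict 78.0 and 437. Fcgr3, a close relative next to Fcgr2b, had 109 UMIs where 22.2 were expected, and the Fcgr2b to Fcgr3 ratio was 1.06 in T cells and 0.713 in macrophages but 7.33 (3.11 to 21.1) in plasmacytoid dendritic cells, so reads shared by both genes may contribute in T cells and would not account for plasmacytoid dendritic cells, and transcripts altered around a deletion were not tested. An exchange of the library labels might be thought of, since the wild-type library has only 2 UMIs in the CD8, conventional CD4 and regulatory T cell classes, 1 in cycling CD8 T cells (40 in the other library) and 8 in mixed T cells (10.1 and 29.5 CPM). The 416 Fcgr2b UMIs in wild-type macrophages cannot settle this, because the deleted part is not known, but Fcgr2b is lower in the library labelled Fcgr2b knockout, as the labels would have it, in microglia (ratio 0.348), the monocyte cluster (0.488), B or plasma cells (0.642) and macrophages (0.682), and not in type 2 conventional (122 and 127 CPM) or migratory dendritic cells (3.02 and 20.2).

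In 46 genes, the libraries differed in the same direction in at least 6 of 11 classes. A chromosome 1 segment around Fcgr2b from another mouse strain, carried along with the knockout, may explain some. Within 5 Mb of Fcgr2b lie 4 of the genes, Ifi202b among them, more than the mean of 0.608 in 10000 random sets. The rule asked for more than the maximum of those sets, 6, so it could not decide, and the segment stays open for these. That maximum does not tell how rarely a random set has 4. Most of the genes cannot lie within such a segment, because only 11.1% of those with coordinates are on chromosome 1. Effects of a segment on genes elsewhere were not tested. Free RNA that differs between the libraries, as sized from macrophage genes, could reach 8.7% of the genes in CD8 T cells. That sizing cannot exclude free RNA of other cells, such as that of the mast cell gene Mcpt1 (27.8 and 1.99 CPM in CD8 T cells). The other classes were not examined in this way. A strain difference elsewhere in the genome and a difference in library preparation, which the order by transcript length is consistent with, remain possible and were not tested; the labels give polyA RNA for the wild-type library and total RNA for the other.

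Macrophages or monocytes had a 4.46-fold higher share in the library labelled Fcgr2b knockout. Cells with few genes might have inflated it, but the ratio was still 4.01 (3.58 to 4.52) with at least 500 genes per cell. Whether doublets contribute was not tested; the automatic doublet threshold gave 3.76. If macrophages had only been added to a like mixture, other classes would keep their ratios to each other, but outside the class NK cells had a ratio of 0.327 (0.289 to 0.370) and CD8 T cells 1.75 (1.57 to 1.96). The genotype itself, tumour size, the pooling of 5 brains and differences in sorting are each possible and cannot be separated with 1 library per genotype.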
